A study of Homo sapiens with 25 samples.

How the data were processed

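Poly-A RNA from human H1 embryonic stem cells was sequenced in 25 libraries. The first experiment holds primed wild-type cells in mTeSR medium at passage 43, naive wild-type, KLF4-knockout and KLF5-knockout cells in FINE medium at passage 11, and naive cells with both knockouts at passage 12, with 3 libraries per group. Per the labels, the knockouts were made by CRISPR-Cas9 in primed cells, which were then adapted to naive culture. The second holds primed cells between passages 45 and 50, taken 3 days after transfection with a KLF5 expression vector or its control (3 libraries each) or with CRISPR activation of LTR7Y or its control (2 libraries each). The labels do not say whether replicates were separate cultures, and they do not mention feeder cells.

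The deposited gene files hold read-pair counts per gene that the authors made with featureCounts over whole gene bodies, introns included, without regard to strand. The deposited repeat files hold counts per repeat copy from the same tool, in which a read that maps to several copies was counted at each. The submitters' processing notes name cutadapt 1.18, FastQC 0.11.8, STAR 2.7.0e, featureCounts 2.0.0 and DESeq2 1.26.0, an Ensembl protein-coding annotation and a repeat annotation, both on GRCh38. The gene files list 19986 genes, of which 19887 had a symbol in the table pairing identifiers with symbols, 99 had none and 15 shared one. Long non-coding RNAs are outside this annotation. The repeat files list 4693511 copies of 1180 subfamilies, among them 257 copies of LTR7Y, 2418 of LTR7 and 5967 of HERVH-int, and 2007941 copies lie in or overlap a protein-coding gene body. In a GENCODE reference on the same build, 19919 of the gene identifiers were found and 19885 of these overlapped the reference position. Repeat classes are not given in the files, so each subfamily was tested.

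Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood tests on a means model by group, with TMM scaling and filterByExpr at its minimum of 10 counts and total of 15. The 2 experiments were fitted apart, so that each shared 1 estimate of spread. The Benjamini-Hochberg adjusted p had to fall under 0.05. Comparisons were naive against primed wild type, each of the 3 knockout lines against naive wild type, the KLF5 knockout against the KLF4 knockout, the departure of the double knockout from the sum of the single ones (interaction), KLF5 overexpression against its control, and CRISPR activation against its control. Repeat subfamilies, summed over copies, were tested in the same way with the scaling of the gene counts. Single copies of the LTR7 and HERVH subfamilies were tested together, and the LTR7Y copies called were counted. CPM values are TMM-scaled counts per library, given as mean ± SD. Folds against a group at 0 used a floor of 3 counts over the group, and folds against 1 to 3 counts have a 95% counting interval. Principal components were taken from log2 CPM with 1 added.

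Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over the 216 tests of 27 lists and 8 comparisons. The estimated correlation was the alternative, under which 3 of 88 calls held: primed markers in the naive-primed and double-knockout comparisons and naive markers with KLF5 overexpression. The lists were naive, primed and shared pluripotency genes; 8-cell and genome activation genes; trophoblast, primitive endoderm, amnion, mesoderm, neural ectoderm and fibroblast markers; the KLF family; genes known to carry LTR7 or HERVH transcripts; imprinted genes; DNA methylation; transposon silencing; glycolysis; nuclear oxidative phosphorylation; mitochondrially encoded genes; p53 targets; interferon genes; amino acid and ER stress genes; FGF and ERK, WNT, Nodal and BMP targets; cell cycle; and cholesterol and lipid synthesis. The 9 repeat lists were LTR7 and HERVH, LTR5 and HERVK, SVA, LTR12 and HERV9, MLT2 and HERVL, young L1, AluY, trophoblast LTRs, and HERVW with HERV-FRD LTRs.

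The comparisons, tests, lists, named-gene rule and most alternatives were set before the data were examined. The rule named KLF4, KLF5, KLF17, NANOG, POU5F1 and SOX2 everywhere. It added, per comparison, the 6 largest rises and 6 largest falls that passed, with at least 5 CPM in the higher group, non-overlapping values and a symbol that is not a clone name (3 each way for the interaction). With 3 libraries against 3, chance gives such non-overlap in 10% of genes. From each list it took up to 4 passing members with the largest change and up to 2 others, from repeats the members of the lists and the 4 largest changes each way with at least 100 counts, and 3 LTR7Y copies each way with at least 10 counts. Some genes that the rule names are not reported here. HAND2, FOXF1, TCF21 and other genes of the tests on mesenchymal expression were chosen after the values were seen. Members with reads shared between near-identical paralogs, such as CGB8 and CGB5, MBD3L2 and MBD3L3, TRIM49, H3Y1, and ALPG and ALPP, have uncertain individual levels.

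Overlaps between comparisons used Fisher exact tests, two-sided, adjusted over 10 pairs, with Pearson and Spearman correlations across genes. Where comparisons shared libraries, the covariance was set beside that of 20 simulated draws in which no gene changed. Alternatives were DESeq2 1.42.0, RLE size factors, no count filter, the replicate number as a block, only the groups compared, leaving out each library, scaling from repeats or from the LTR7 and HERVH copies, leaving out the top copy of each subfamily, higher count minimums and the estimated list correlation. Copies outside gene bodies, and leave-outs for the overlaps, were added after the data were seen. Tables were handled with version 1.17.8 of data.table, pandas 2.3.3, numpy 2.4.6 and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

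In simulations from these libraries, 3 naive against 3 recovered 65.7% of genes changed 2-fold and 96% of those changed 4-fold, with 3.61% false calls. The KLF5 overexpression design gave 91.9%, 98% and 5.97%, and the CRISPR activation design, with 2 libraries per arm, gave 81.6%, 96% and 8.81%. The list test found the changed list and called 1 of 50 unchanged lists, but correlation within lists was not simulated.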

Results

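Human H1 embryonic stem cells were profiled by poly-A RNA sequencing in 25 libraries from 9 groups. The first experiment had 15 libraries, 3 per group: primed and naive wild-type cells and naive cells with knockout of KLF4, KLF5 or both. The 10 libraries of the second experiment came from primed cells 3 days after transfection. They comprised KLF5 overexpression and its control (3 each), and CRISPR activation aimed at the LTR7Y repeat and its control (2 each). KLF4, KLF5 and KLF17 are Krüppel-like transcription factors of the naive state, and LTR7Y is an endogenous retroviral long terminal repeat that is active in the early human embryo. Comparisons asked which genes and repeat subfamilies followed the cell state or a factor, and which moved with KLF5 or LTR7Y driven in primed cells. The gene files held 16606021 to 30654400 counts per library and the repeat files 3259254 to 8720264. Gene levels are given in CPM (mean ± SD) and changes as log2 fold change ± SE, with Benjamini-Hochberg adjusted p-values from edgeR. Repeat levels are in CPM of the gene counts. Those p-values measured the spread between these samples alone, since the labels do not say whether the replicates were separate cultures. Intervals and lower bounds on fold changes covered counting error alone.

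The first principal component, with 64.3% of the variance, separated primed from naive libraries, and the second held 10.3%. The naive wild-type and KLF4-knockout libraries lay at 107.9 to 113.1 on the first component. The KLF5-knockout libraries stood apart on the second component, at -83.3 to -65.7, and the double-knockout libraries lay between the primed and naive groups at 17.6 to 28.3. In the second experiment, CRISPR activation moved primed cells from about -76.9 to -50.3 and -53.1, and KLF5 overexpression moved them to between -65.8 and -63.8.

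**Figure D1:**
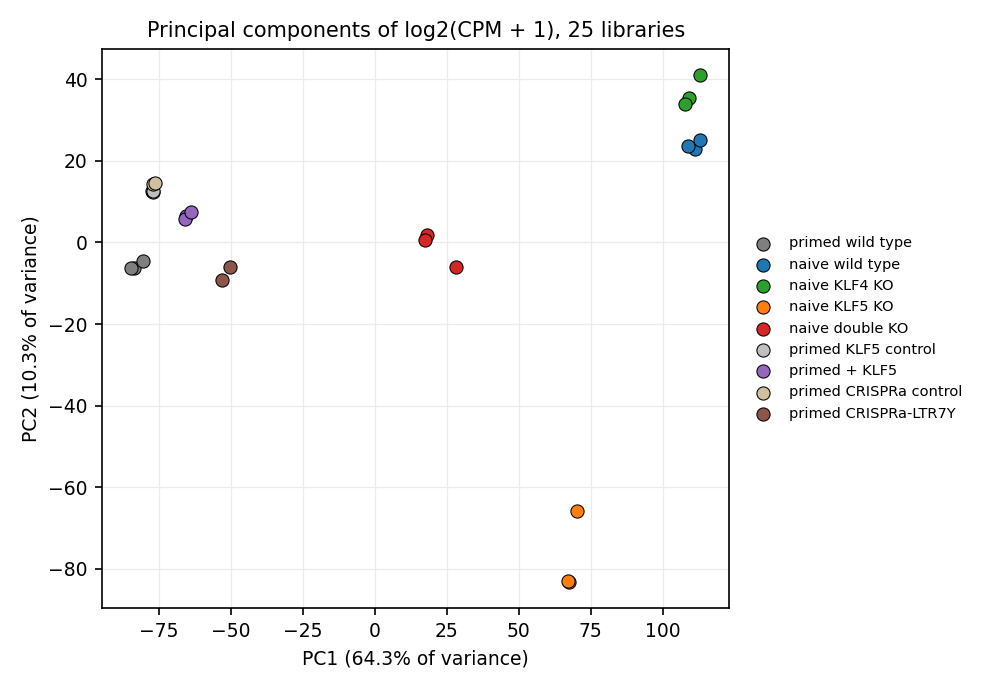
Each point is 1 of the 25 libraries, placed by its scores on principal component 1 (64.3% of variance, horizontal axis) and principal component 2 (10.3%, vertical axis) of log2 gene CPM. Colour gives the group.

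KLF4 (ENSG00000136826, chromosome 9, 107484852 to 107490482) and KLF5 (ENSG00000102554, chromosome 13, 73054976 to 73077541) were read first in each library. Positions are on GRCh38. KLF4 stood at 284, 351 and 313 CPM in the naive wild-type libraries and at 130, 149 and 151 CPM in the KLF4-knockout libraries. In the KLF5-knockout libraries it read 153, 143 and 142 CPM, and with both factors knocked out 64.5, 80.1 and 68 CPM. KLF5 stood at 226, 235 and 226 CPM in naive wild-type cells, at 77.3, 86.6 and 99.5 CPM in the KLF5 knockout, and at 56.6, 48.5 and 56.8 CPM in the knockout of both. With KLF4 knocked out KLF5 read 268, 267 and 285 CPM. The knockout lines therefore kept transcripts of the targeted genes, and these gene counts carry no measure of the proteins. Overexpression took KLF5 from 3.59, 3.59 and 3.51 CPM to 883, 821 and 804 CPM.

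**Figure D2:**
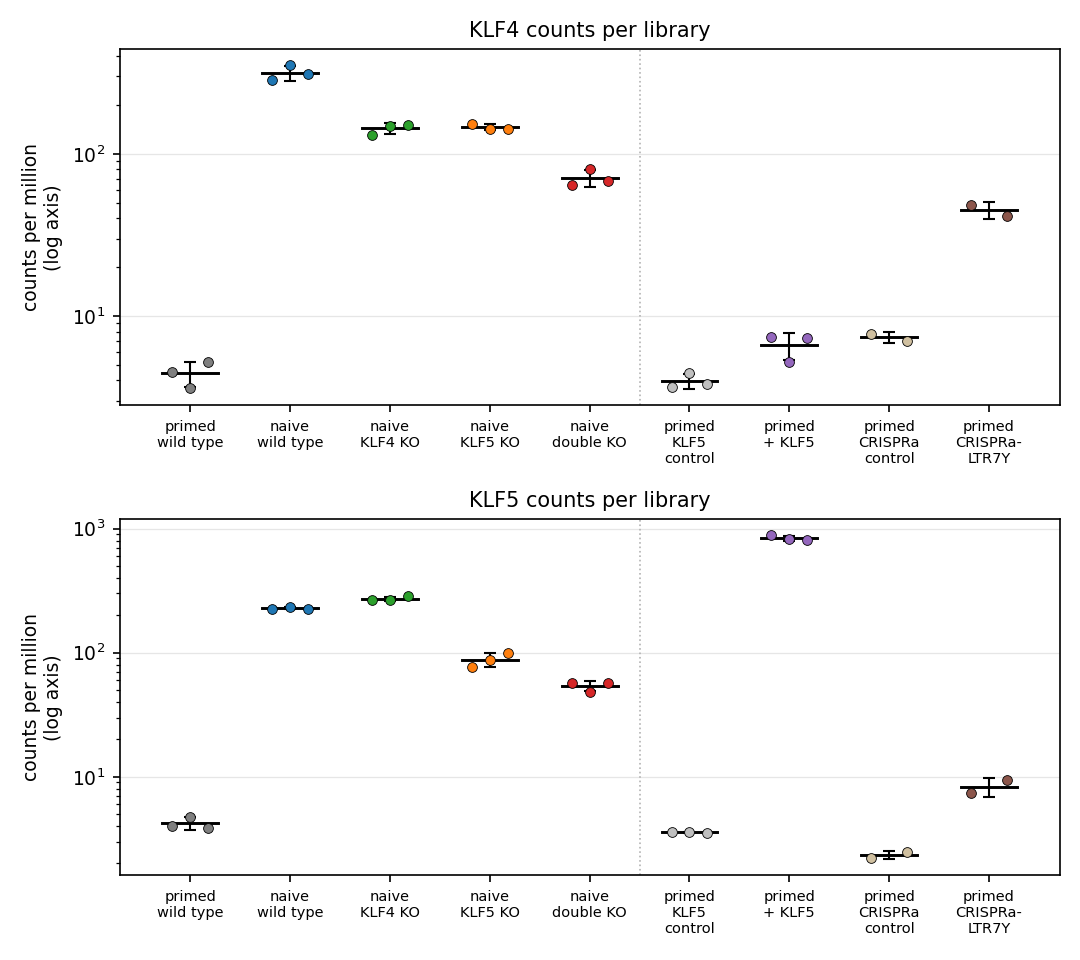
KLF4 and KLF5 in separate panels, in CPM on a log axis across the 9 groups. Points are libraries, bars are group means and error bars are the SD.

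Naive wild-type cells differed from primed wild-type cells in most measured genes. Naive, trophoblast and amnion markers rose, while primed markers fell. Only the primed list kept its call with an estimated correlation. Of 15572 genes tested, 5971 rose and 6348 fell, and 7784 of the 12319 changed at least 2-fold. KLF4 rose by 6.16±0.15 (316±34 against 4.43±0.79 CPM; adjusted p = 3.13e-15), KLF5 by 5.76±0.13 (229±5.03 against 4.21±0.493 CPM; adjusted p = 1.37e-15) and KLF17 (ENSG00000171872, chromosome 1, 44118850 to 44135140) by 7.14±0.40 (adjusted p = 3.22e-11). NANOG, a homeobox factor of the pluripotency network (ENSG00000111704, chromosome 12, 7787794 to 7799146), rose by 1.65±0.13 from 56.1±5.27 to 176±9.4 CPM (adjusted p = 2.1e-09). POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731) rose by 0.62±0.10 (adjusted p = 2.36e-05). SOX2 (ENSG00000181449, chromosome 3, 181711925 to 181714436) moved the other way, by -2.14±0.14 (adjusted p = 2.69e-10). CGA, which encodes the common chain of the glycoprotein hormones, reached 1030±122 CPM and was at least 26600-fold higher. MRGPRX1 was at least 9410-fold higher, the steroidogenic enzyme gene HSD3B1 at least 8130-fold, ZNF729 at least 4950-fold and ZNF257 at least 3220-fold. The chorionic gonadotropin gene CGB8, one of a set of near-identical paralogs, was 27300-fold higher (95% counting interval 4910 to 1080000), and its fitted log2 change moved from 14.17 to 15.75 without primed wild-type library 2. Among the falls, the WNT antagonist SFRP2 was 28500-fold lower (interval 5110 to 1130000), with a fitted log2 change of -14.38 that moved to -16.42 without naive library 2. COL9A1 was at least 683-fold lower, C1orf94 at least 424-fold lower and LIN7A at least 335-fold lower. THY1, a surface marker of primed cells, fell by 12.45 and by 13.07 without naive library 1.

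Naive pluripotency markers rose as a set and primed markers fell. Trophoblast and amnion markers also rose, as did DNA methylation genes. Of 25 naive markers 23 rose and 2 did not pass (24 rose adjusted over the list alone), with a camera adjusted p = 3.48e-09, and adjusted p = 0.0991 with an estimated correlation. Examples were the oocyte factor KHDC3L (11.22±0.29; 171 against 0.0662 CPM), DPPA5 (9.31±0.20) and the maternal-effect gene NLRP7 (8.99±0.16; 2550 against 4.99 CPM). Of 24 primed markers 22 fell and 2 rose, also adjusted over the list alone (adjusted p = 3.7e-07 by camera, and adjusted p = 0.0399 with an estimated correlation), led by PTPRZ1 at -10.03±0.23 and ZIC5 at -9.24±0.26. Trophoblast markers rose in 22 of 24, with 1 fall, and the counts were the same adjusted over the list alone. Their camera adjusted p = 7.79e-07 was lost at adjusted p = 0.333 with an estimated correlation; GATA2 rose by 10.95±0.39 to 1050 CPM and VGLL1 was at least 1230-fold higher. Amnion markers rose in 13 of 14 and fell in 1, also adjusted over the list alone (adjusted p = 0.000347, and adjusted p = 0.185 with an estimated correlation), among them MSX2 (9.63±0.49) and VTCN1 (5.69±0.29). DNA methylation genes rose in 10 of 12 and fell in 2, also adjusted over the list alone (adjusted p = 0.0192, and adjusted p = 0.15 with an estimated correlation), led by the methyltransferase cofactor DNMT3L at 7.43±0.22. KLF family genes rose in 12 of 17, fell in 3 and did not pass in 2 cases, also adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.15 with an estimated correlation); KLF12 fell by 4.79. The 8-cell stage genes rose in 10 of 13, with 1 fall and the same counts adjusted over the list alone, at a median of 6.68 that was 4.04 when members absent from primed cells were held at their lower bound (adjusted p = 0.0158, and adjusted p = 0.149 with an estimated correlation). ZNF280A was at least 207-fold higher and KDM4E at least 72.7-fold higher.

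Cholesterol synthesis genes rose in 15 of 20 and fell in 4, also adjusted over the list alone (adjusted p = 0.00682 by camera, and adjusted p = 0.422 with an estimated correlation), with HMGCS1 at 3.45±0.13 and INSIG1 at 3.33. Cell-cycle genes rose in 14 of 22, fell in 3 and did not pass in 5, also adjusted over the list alone (adjusted p = 0.0331, and adjusted p = 0.571 with an estimated correlation), with CCNE1 at 3.71 and PCNA at 1.76. Nodal pathway genes rose in 7 of 10 and fell in 2, also adjusted over the list alone (adjusted p = 0.0357, and adjusted p = 0.445 with an estimated correlation), with LEFTY2 at 4.61 and SMAD7 at 3.26. FGF and ERK response genes rose in 6 of 17 and fell in 9 (camera adjusted p = 0.234), with ETV1 at -6.71, DUSP6 at -6.13 and IER3 at 4.03. Fibroblast and mesenchyme markers fell in 10 of 16 and rose in 4 (adjusted p = 0.202), including COL1A1 at -4.62 and VIM at -4.07, while TWIST1 rose by 5.76.

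Retroviral repeats diverged within 1 family. HERVH-int is the internal part of a primate endogenous retrovirus, LTR7 is its usual terminal repeat, and LTR7Y is the variant of the early embryo. LTR7Y rose by 2.32±0.13 in naive cells, from 32.2±2.3 to 161±19.7 CPM (adjusted p = 8.41e-13), whereas HERVH-int fell by 1.75±0.09, from 28700±969 to 8540±702 (adjusted p = 1e-13), and LTR7 fell by 2.27. LTR7B rose by 0.67, LTR7A fell by 4.37, and LTR7C fell by 0.26, a call lost without primed libraries 1 (0.0955), 2 (0.0726) or 3 (0.0787) or naive libraries 1 (0.15) or 3 (0.225). In the second family, HERVK-int rose by 2.57±0.13 to 4590 CPM, with its terminal repeats LTR5_Hs at 2.25 and LTR5 at 3.75. Across subfamilies 309 of 1106 rose and 402 fell (379 and 363 with scaling from repeats), led by LTR10B2 (4.51), MER50-int (4.42) and MER66-int (4) among rises and by MER136 (-5.31), MER61D (-4.21), LTR108d_Mam (-4.03) and REP522 (-3.51) among falls. Counted over copies outside gene bodies, LTR10B2 read -0.19 and MER66-int -0.98, so their rises came from copies inside genes. Of 39 LTR7Y copies with enough counts 27 rose and 7 fell, but 35 rose and 1 fell with scaling from the LTR7 and HERVH copies. A copy on chromosome 5 (180415688 to 180416157) was at least 478-fold higher and one on chromosome X (109866074 to 109866543) at least 266-fold higher. An intronic copy in TPTEP1 (chromosome 22, 16614709 to 16615149) held 1321 counts against 1. In the gene scaling, lower copies included one on chromosome 20 (12340267 to 12340700), at least 15.1-fold lower, and an intronic copy in NTN4 (chromosome 12, 95748862 to 95749284) at -3.22. Multi-mapped reads were counted at each copy and strand was ignored, so similar or neighbouring copies and overlapping or antisense genes could not be separated.

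**Figure D3:**
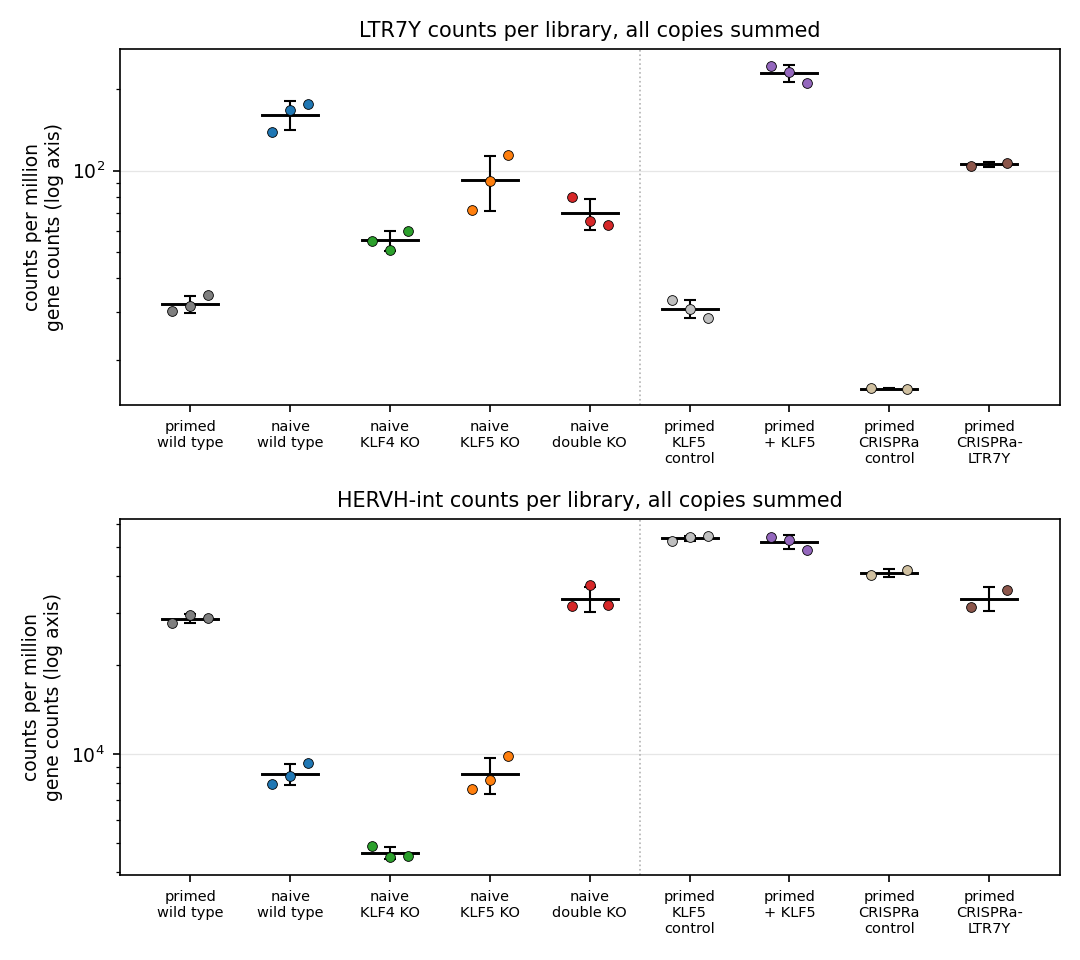
LTR7Y and HERVH-int in CPM of the gene counts on a log axis across the 9 groups. Points are libraries, bars are group means and error bars are the SD.

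Naive KLF4-knockout cells had lower naive, 8-cell and Nodal pathway genes and higher p53 targets. None of these list calls held with an estimated correlation. Large falls included the imprinted retrotransposon-derived gene RTL1, the WNT ligand enhancer RSPO3, the integrin gene ITGAM and KLF17. Against naive wild-type cells 3906 genes rose and 3672 fell, 2541 of them at least 2-fold. KLF4 itself fell by 1.14±0.11 (adjusted p = 9.22e-07). KLF17 fell by 4.13±0.31, from 8.27±1.5 to 0.459±0.289 CPM (adjusted p = 4.3e-08), and NANOG by 1.41±0.13, from 176±9.4 to 66.3±1.89 CPM (adjusted p = 2.63e-07). POU5F1 (-0.61, adjusted p = 0.000114) and SOX2 (-0.64, adjusted p = 0.00112) also fell. KLF5 rose by 0.26±0.10 (adjusted p = 0.0405), a call lost without any one of the compared libraries, at adjusted p = 0.0777 to 0.139. RTL1 fell by 6.52 and by 7.18 without KLF4-knockout library 1. ITGAM (-4.64±0.30), RSPO3 (-4.22±0.53), TWIST2 (-4.11±0.28) and the prohormone convertase gene PCSK1 (-4.10±0.37) completed the largest falls. Rises were led by the interferon-inducible surface gene BST2, 236-fold higher (95% counting interval 64.9 to 1950), and the adhesion gene NCAM2 at 6.08, which read 7.26 without naive library 3. BNIP5 rose by 5.40 and by 4.59 without KLF4-knockout library 3. NGFR (4.87±0.45), HOXB1 (4.02±0.39) and ATP1B2 (3.92±0.47) followed.

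With KLF4 knockout naive markers fell in 17 of 25, rose in 2 and did not pass in 6, also adjusted over the list alone (adjusted p = 5.49e-06 by camera, and adjusted p = 0.152 with an estimated correlation), including KHDC3L (-3.54±0.16; 14.6 against 171 CPM) and GDF3 (-1.92±0.13). Nodal pathway genes fell in 8 of 10 (adjusted p = 0.00013, and adjusted p = 0.176 with an estimated correlation), also adjusted over the list alone, with LEFTY1 at -3.77±0.32 and NODAL at -2.21±0.14 (37.3 against 173 CPM). WNT targets fell in 10 of 12 and rose in 1 (11 fell adjusted over the list alone), at a median of -1.33 that was -1.24 at the lower bounds (adjusted p = 0.00029, and adjusted p = 0.139 with an estimated correlation), among them CDX1 at -2.13±0.33 and NKD1 at -1.64. BMP targets fell in 6 of 10 (7 adjusted over the list alone; adjusted p = 0.00362, and adjusted p = 0.333 with an estimated correlation), led by ID4 (-2.03) and SMAD6 (-1.97±0.16). The 8-cell genes fell in 7 of 13 and rose in 1, also adjusted over the list alone (adjusted p = 0.00682, and adjusted p = 0.126 with an estimated correlation). TRIM49 was at least 17.8-fold lower, MBD3L3 at least 11-fold lower and MBD3L2 at least 10.6-fold lower, in paralog families whose reads are hard to assign. Shared pluripotency genes fell in 9 of 13 and rose in 2, also adjusted over the list alone (adjusted p = 0.0123, and adjusted p = 0.501 with an estimated correlation), with FOXD3 at -1.80±0.27 and L1TD1 at -1.34±0.21. KLF genes, KLF4 included, fell in 11 of 17 and rose in 2, also adjusted over the list alone, with KLF3 at -1.54±0.16. Adjusted p was 0.00737 (0.152 with an estimated correlation). Transposon control genes fell in 12 of 23 and rose in 3, also adjusted over the list alone (adjusted p = 0.0146, and adjusted p = 0.174 with an estimated correlation), including ZNF534 (-1.64±0.18). Trophoblast markers did not pass as a list with KLF4 knockout (4 rose and 6 fell of 24; adjusted p = 0.867), and between the knockout lines they were lower with KLF5 knockout in 20 of 24 and higher in 2 (20 and 3 adjusted over the list alone; adjusted p = 6.07e-08, and adjusted p = 0.283 with an estimated correlation).

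Lists that rose with KLF4 knockout were p53 targets, nuclear respiratory genes and glycolysis genes, none with an estimated correlation. Of 17 p53 targets 13 rose and 4 did not pass, also adjusted over the list alone (adjusted p = 0.000419 by camera, and adjusted p = 0.252 with an estimated correlation), with GDF15 at 1.26±0.20, CDKN1A at 1.09±0.18 and FDXR at 1.03. Oxidative phosphorylation genes rose in 14 of 25 and fell in 2 (15 and 3 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.475 with an estimated correlation), with ATP5F1C at 1.11±0.15. Glycolysis genes rose in 9 of 18 and fell in 2, also adjusted over the list alone (adjusted p = 0.0393, and adjusted p = 0.548 with an estimated correlation), with PFKM at 1.71±0.13. Mitochondrially encoded genes went the other way in 6 of 13 and did not pass in 7, also adjusted over the list alone (adjusted p = 0.186). LTR7Y fell by 1.54±0.13 to 55.3±4.61 CPM (adjusted p = 1.29e-08), HERVH-int by 0.88 and HERVK-int by 1.24, while LTR7 fell by 0.43 and LTR5_Hs by 0.82. Across subfamilies 126 rose, led by MLT1G-int (1.81), UCON67 (0.93), MST-int (0.93) and Charlie21a (0.85), and 160 fell, among them L1P3b (-2.14), MER34-int (-1.64) and SST1 (-1.56). MLT1G-int read -0.02 outside gene bodies and L1P3b 0.45 without its top copy. The total of 286 dropped to 174 without naive library 2 and to 181 without KLF4-knockout library 3. Of 39 LTR7Y copies 26 fell and 2 rose (20 and 5 with scaling from LTR7 and HERVH copies). A copy on chromosome 1 (228951501 to 228951887) was at least 39.1-fold lower, one on chromosome 11 (20572215 to 20572655) at least 14.1-fold lower, and one on chromosome 7 (26024200 to 26024639) held 1 count against 178. Copies on chromosome 13 (90839564 to 90839993; 1.86) and chromosome 16 (86280841 to 86281279; 1.31) rose.

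Naive KLF5-knockout cells had higher mesenchymal and interferon genes and lower trophoblast markers. None of these list calls held with an estimated correlation. Library 3 of this knockout lay at -65.7 on the second component, apart from the other libraries at -83.3 and -83. In total 4482 genes rose and 3781 fell, 3581 of them at least 2-fold. KLF5 fell by 1.38±0.10 (87.8±11.1 CPM; adjusted p = 6.51e-09) and KLF4 by 1.11±0.11 (146±6.24 CPM; adjusted p = 4.48e-07). KLF17 rose by 1.34±0.22 to 20.9±1.72 CPM (adjusted p = 5.85e-05), opposite to its fall with KLF4 knockout, and the direct comparison of the knockout lines put it 5.48 higher with KLF5 knockout (adjusted p = 1.79e-10). POU5F1 fell by 0.43 (adjusted p = 0.00154) and SOX2 did not pass (0.12, adjusted p = 0.462). NANOG fell by 0.32±0.12 (adjusted p = 0.0363), a call lost without naive library 2 (0.125) or KLF5-knockout libraries 1 (0.105) and 2 (0.083). HGF reached 661±208 CPM from 0.218±0.133 (11.46±0.36), and the proteoglycan gene DCN reached 277±114 CPM (10.96±0.46, or 12.04 without naive library 1). SAMD9L was at least 254-fold higher, WFDC1 at least 187-fold and IL18R1 at least 145-fold. BST2 was 1470-fold higher (95% counting interval 408 to 12200). Falls were led by LAIR2 (-3.85), CD48 (-3.61±0.34; 22.5 against 275 CPM), the placental peptide gene INSL4 (-3.43±0.32; 2.89 against 31.3 CPM), LEP (-3.39±0.32), PSG9 (-3.38±0.32) and ISM2 (-3.30±0.37).

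Every fibroblast and mesenchyme marker in the list, 16 of 16, rose, also adjusted over the list alone (adjusted p = 2.12e-11 by camera, and adjusted p = 0.169 with an estimated correlation). COL3A1 went from 8.75±2.54 to 9050±2900 CPM (10.01±0.55), LUM from 1.95 to 1230±375 CPM (9.29±0.36), and POSTN rose by 9.29±0.33. Imprinted genes rose in 11 of 14 and fell in 2, also adjusted over the list alone (adjusted p = 0.000824, and adjusted p = 0.252 with an estimated correlation), with DLK1 at 8.96±0.39 (2290±1050 CPM) and PLAGL1 at 6.77±0.29. Mesoderm genes rose in 11 of 14 (12 adjusted over the list alone; adjusted p = 0.00205, and adjusted p = 0.333 with an estimated correlation), including SNAI2 at 3.99±0.23. Primitive endoderm markers rose in 11 of 17 and fell in 3 (12 and 3 adjusted over the list alone; adjusted p = 0.00737, and adjusted p = 0.333 with an estimated correlation), with GATA4 at 5.61±0.27 and PDGFRA at 3.68±0.23 against APOA2 at -2.97. Interferon genes rose in 14 of 16 (15 adjusted over the list alone; adjusted p = 0.000494, and adjusted p = 0.515 with an estimated correlation), and IFI44L was at least 93.2-fold higher. Primed markers rose in 15 of 24 and fell in 4 (16 and 4 adjusted over the list alone; adjusted p = 0.0318, and adjusted p = 0.217 with an estimated correlation), with CDH2 at 6.38±0.52 and FAT3 at 5.85±0.35.

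Trophoblast, naive and cell-cycle lists fell with KLF5 knockout by camera, but not with an estimated correlation. Trophoblast markers fell in 20 of 24 (20 fell and 1 rose adjusted over the list alone), with camera adjusted p = 2.84e-08, and adjusted p = 0.279 with an estimated correlation. The angiogenic factor gene PGF fell by 2.85±0.26 (338 against 2430 CPM), the syncytin gene ERVW-1 by 2.55±0.30 (164 against 964 CPM), KRT7 by 2.59±0.14 and DLX3 by 2.53±0.28. Naive markers fell in 17 of 25 and rose in 3 (19 and 3 adjusted over the list alone; adjusted p = 9.73e-05, and adjusted p = 0.185 with an estimated correlation), including TFAP2C at -1.88±0.14 (121 against 446 CPM). FGF and ERK response genes fell in 12 of 17 and rose in 4, also adjusted over the list alone (adjusted p = 0.0053, and adjusted p = 0.205 with an estimated correlation), with DUSP4 at -3.10±0.21 and SPRY4 at -3.07±0.18 against SPRED1 at 2.77. DNA methylation genes fell in 8 of 12 (9 adjusted over the list alone; adjusted p = 0.000719, and adjusted p = 0.0928 with an estimated correlation), including DNMT1 at -1.09±0.16. Cell-cycle genes fell in 14 of 22, also adjusted over the list alone (adjusted p = 0.00101, and adjusted p = 0.368 with an estimated correlation), with MCM3 at -0.71 and the growth inhibitor gene CDKN1C at -1.55. Cholesterol genes fell in 9 of 20 and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0207, and adjusted p = 0.501 with an estimated correlation), with FASN at -0.67.

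LTR7Y fell by 0.80±0.13 with KLF5 knockout, to 92.4±21.2 CPM (adjusted p = 6.22e-05). HERVH-int (0.00, adjusted p = 0.988), LTR7 (0.00, adjusted p = 0.987) and HERVK-int (-0.27, adjusted p = 0.122) did not pass, and LTR7C fell by 0.45, LTR5_Hs by 0.47 and LTR5 by 1.66. Satellite repeats led the 90 subfamily rises, with HSAT4 at 1.92, ALR/Alpha at 1.76, REP522 at 1.61 and HSAT5 at 1.21. The 159 falls included LTR10B2 (-2.80), MER50-int (-2.53), MER66-int (-2.26) and HERVIP10B3-int (-2.10), and with scaling from repeats 145 rose and 137 fell. Outside gene bodies LTR5 read 0.69, LTR10B2 0.08 and MER66-int 0.15. Without KLF5-knockout library 1 the total of 249 subfamilies dropped to 164. Of 39 LTR7Y copies 18 fell and 0 rose, led by copies on chromosome 9 (82701562 to 82702002; -4.94), in an intron of CALB1 (chromosome 8, 90090224 to 90090657; -3.71) and in an intron of NTN4 (chromosome 12, 95754458 to 95754890; -3.57). Without KLF5-knockout library 1 it was 11 copies.

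Double-knockout cells in naive culture lay closer to primed expression than naive wild-type cells did. The knockouts were made in primed cells before adaptation, so these values do not show a change after it. Primed markers rose, and trophoblast and amnion markers fell, though these 2 lists lost their calls with an estimated correlation. Library 2 of this knockout stood apart. Its chi-square per degree of freedom was 73.3 and 68.9 against the other libraries, which gave 3.66 with each other, and mitochondrially encoded genes held 9.9% of its counts against 5.76% and 5.86%. Of the called genes 5333 rose and 4921 fell, with 5086 changing at least 2-fold. KLF4 fell by 2.16±0.12 (70.8±8.21 CPM; adjusted p = 1.51e-10), KLF5 by 2.08±0.10 (54±4.71 CPM; adjusted p = 4.49e-11) and KLF17 by 2.21±0.25 (1.78±0.317 CPM; adjusted p = 6.54e-07). POU5F1 rose by 0.71±0.10 (adjusted p = 9.87e-06) and SOX2 by 1.80±0.14, from 133 to 462 CPM (adjusted p = 7.87e-09). NANOG rose by 0.29±0.12 (adjusted p = 0.0451), a call lost without double-knockout libraries 1 (0.209) and 3 (0.183) or naive libraries 1 (0.177) and 3 (0.13). SFRP2 was 1750-fold higher (95% counting interval 313 to 69000), its fitted log2 change moving from 10.34 to 12.36 without naive library 2. BST2 was 1310-fold higher (interval 362 to 10800). THY1 rose by 9.54±0.35 to 75.4 CPM, and by 10.19 without naive library 1. The germ-cell RNA-binding gene RBM46 was 623-fold higher (interval 112 to 24700; 8.87, or 10.87 without naive library 1). NTS rose by 7.90, and by 7.10 without double-knockout library 2. That library also set the size of several falls, which without it grew from -5.90±0.38 to -6.96 for SLC6A19, from -5.66 to -6.80 for CARD16, from -5.45 to -6.62 for PRR9, from -5.37 to -5.98 for APOL4 and from -5.36 to -6.10 for GABRR2. GSTA3 fell by 5.12±0.31 (0.445 against 15.6 CPM).

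Primed markers rose in 21 of 24 and fell in 2, also adjusted over the list alone, and this list kept its call under both settings (adjusted p = 2.03e-07 by camera, and adjusted p = 0.0399 with an estimated correlation); PTPRZ1 rose by 7.78±0.22 (130 against 0.576 CPM). Shared pluripotency genes rose in 12 of 13, also adjusted over the list alone (adjusted p = 0.000227, and adjusted p = 0.333 with an estimated correlation), including LIN28A (1.70±0.16) and DPPA4 (1.69±0.11). Trophoblast markers fell in 21 of 24, also adjusted over the list alone (adjusted p = 7.35e-10, and adjusted p = 0.223 with an estimated correlation), with CGB5 at -4.56±0.20, PGF at -4.39±0.28 and KRT7 at -3.99±0.15. Naive markers fell in 20 of 25 and rose in 2, also adjusted over the list alone (adjusted p = 3.41e-06, and adjusted p = 0.15 with an estimated correlation), with SUSD2 at -2.64±0.12 and DNMT3L at -2.42±0.15. Amnion markers fell in 10 of 14 and rose in 1, also adjusted over the list alone (adjusted p = 0.000923, and adjusted p = 0.223 with an estimated correlation), led by VTCN1 (-3.47±0.25) and HEY1 (-3.20±0.23). The 8-cell genes fell in 9 of 13, also adjusted over the list alone (adjusted p = 0.0139, and adjusted p = 0.141 with an estimated correlation), with KDM4E at -2.55±0.41. Primitive endoderm markers fell in 11 of 17 and rose in 1, also adjusted over the list alone (adjusted p = 0.0335, and adjusted p = 0.428 with an estimated correlation), with HNF4A at -2.53±0.18. Fibroblast markers rose in 9 of 16 and fell in 1 without passing as a list (adjusted p = 0.19), with VIM at 5.30±0.33.

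HERVH-int rose by 1.97±0.09 in the double-knockout cells, to 33500±3200 CPM (adjusted p = 8.32e-14), and LTR7 rose by 2.12 to 2960 CPM, while LTR7Y fell by 1.21±0.13 to 69.5±9.24 (adjusted p = 6.64e-08). LTR7B fell by 0.38. LTR5_Hs rose by 0.39 and LTR5 fell by 2.08. HERVK-int rose by 0.35 (adjusted p = 0.023), a call lost without double-knockout library 3 (0.0644) or naive library 2 (0.113). Subfamilies rose in 229 cases, led by Charlie21a (3.11), UCON35 (2.92) and MLT1G-int (2.10), and fell in 242 (299 and 240 with scaling from repeats). The largest falls were MER66-int (-3.20), LTR10B2 (-3.05), HERV17-int (-2.55), the internal part of the syncytin family, and MER50-int (-3.05, or -3.68 without double-knockout library 2). Outside gene bodies HERVK-int read -0.05, LTR5 0.53, LTR10B2 0.52 and HERV17-int 1.67, and HERV17-int read 0.23 without its top copy. Of 39 LTR7Y copies 23 fell and 3 rose, but 38 fell and 0 rose with scaling from LTR7 and HERVH copies. The chromosome 11 copy at 20572215 was at least 16.8-fold lower, an intronic copy in DPH6 (chromosome 15, 35243404 to 35243837) held 2 counts against 69, the CALB1 copy fell by 4.23, and a copy on chromosome 22 (38396539 to 38396797) rose by 1.75 in the gene scaling alone.

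Set directly against the KLF4 knockout, KLF5-knockout cells were higher in fibroblast markers, WNT targets and Nodal genes and lower in trophoblast markers and respiratory genes. None of these list calls held with an estimated correlation. WNT2, HGF and the imprinted growth regulator DLK1 stood at the top, and the vacuolar proton-pump gene ATP6V0D2 and HLA-G among the lowest. With 4666 genes higher and 4132 lower, WNT2 was 5290-fold higher (95% counting interval 949 to 209000), its fitted log2 change moving from 12.01 to 14.04 without KLF4-knockout library 2. OR51E2 was at least 442-fold higher. HGF was higher by 11.94, and by 13.25 and 11.34 without KLF4-knockout libraries 2 and 3. DLK1 (11.39±0.46), COL3A1 (11.18±0.59) and DCN (11.08±0.46) followed. ATP6V0D2 (-5.25±0.39), HAVCR1 (-4.63±0.34; 7.15 against 179 CPM), FAM9C (-4.49±0.27) and HLA-G (-4.48±0.34) were lower, with TMPRSS4 at -4.58 (-5.30 without KLF5-knockout library 3) and BNIP5 at -4.50 (-3.73 without KLF4-knockout library 3). NANOG was higher by 1.09 (adjusted p = 1.33e-06), KLF5 lower at -1.64 (adjusted p = 7.42e-10), SOX2 higher by 0.76 (adjusted p = 0.000158), and KLF4 (0.03, adjusted p = 0.852) and POU5F1 (0.18, adjusted p = 0.143) did not pass. Fibroblast markers were higher in 15 of 16 and did not pass in 1 (16 higher adjusted over the list alone; adjusted p = 2.44e-10 by camera, and adjusted p = 0.168 with an estimated correlation). WNT targets were higher in 10 of 12 (11 adjusted over the list alone; adjusted p = 1.42e-05 by camera, and adjusted p = 0.098 with an estimated correlation), with LEF1 at 4.62±0.24. Nodal genes were higher in 8 of 10 and lower in 1, also adjusted over the list alone (adjusted p = 0.00124, and adjusted p = 0.174 with an estimated correlation), with LEFTY1 at 3.55. Oxidative phosphorylation genes were lower in 19 of 25 and higher in 1 (20 and 1 adjusted over the list alone; adjusted p = 0.000754, and adjusted p = 0.333 with an estimated correlation), with COX5A at -1.36. The 8-cell genes were higher in 10 of 13 and lower in 1, also adjusted over the list alone, at a median of 2.96 and 2.93 at the lower bounds (adjusted p = 0.0238, and adjusted p = 0.152 with an estimated correlation), with KHDC3L at 3.14 among the naive genes. LTR7Y was higher by 0.74 (adjusted p = 0.000143), HERVH-int by 0.88 and HERVK-int by 0.97. HSAT4 (3.41), ALR/Alpha (2.87), HERVS71-int (2.22) and SST1 (1.58) led the 141 higher subfamilies, and MER66-int (-2.70), MER50-int (-2.69), HERV17-int (-2.27) and UCON67 (-1.97) the 201 lower ones, where MER66-int read 0.25 and HERV17-int 0.66 outside gene bodies. With scaling from repeats 198 were higher and 179 lower.

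In all 3 knockouts alike, 1317 genes rose and 1369 fell. Leaving out 1 library at a time gave 2008 to 3288 in all. Of 3421 genes at least 2-fold higher in naive cells 37.9%, 54.9% and 73.8% fell with knockout of KLF4, KLF5 and both. Of others 19.6%, 15.7% and 19.7% fell. Of 4363 genes higher in primed cells 27.8%, 56.3% and 69% rose (others 24%, 18.1% and 20.7%). Those at least 16-fold higher lay a median of 0.004, 0.067 and 0.172 of the way to primed cells. Across genes, which are not independent replicates, the covariance of log2 changes between the naive-primed comparison and the knockout was -0.482 for KLF4, -1.71 for KLF5 and -2.79 for both, where shared controls alone gave about -0.0695 in simulation. Between knockouts the covariance was 1.2 for KLF5 and the knockout of both (90.5% of 6303 genes in the same direction), 0.557 for KLF4 and the knockout of both (79.3% of 5620) and 0.28 for KLF4 and KLF5 (73.2% of 4519), where simulation gave about 0.07. The naive wild-type controls were the same 3 libraries throughout and were too few to divide.

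The change with both knockouts was then set against the sum of the single ones. Line, passage and the source of mesenchymal reads in KLF5-knockout cells were not separated from the knockouts. Shared pluripotency genes stood above that sum, and fibroblast, interferon and primitive endoderm lists below it. None of these list calls held with an estimated correlation. In 3044 genes the combined change was higher than the sum and in 3542 lower. NANOG stood above it by 2.02 (adjusted p = 1.58e-07), POU5F1 by 1.75 (adjusted p = 7.6e-08) and SOX2 by 2.31 (adjusted p = 1.08e-07), while KLF5 stood at -0.96 (adjusted p = 4.1e-05), and KLF4 (0.09, adjusted p = 0.677) and KLF17 (0.58, adjusted p = 0.272) did not pass. Shared pluripotency genes were higher in 13 of 13, also adjusted over the list alone (adjusted p = 1.25e-10 by camera, and adjusted p = 0.139 with an estimated correlation), with FOXD3 at 5.10±0.39 and JARID2 at 2.47±0.16. Fibroblast markers were lower in 12 of 16, also adjusted over the list alone (adjusted p = 1.01e-07, and adjusted p = 0.252 with an estimated correlation), with LUM at -9.49±0.71. Interferon genes were lower in 13 of 16 (14 adjusted over the list alone; adjusted p = 4.3e-05, and adjusted p = 0.445 with an estimated correlation), with BST2 at a fitted -7.89±1.22 over few naive counts, and primitive endoderm markers in 12 of 17 with 1 higher (12 and 2 adjusted over the list alone; adjusted p = 2.4e-05, and adjusted p = 0.152 with an estimated correlation), with GATA4 at -4.87. FGF and ERK response genes were higher in 11 of 17 and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 9.59e-05, and adjusted p = 0.152 with an estimated correlation), with SPRY4 at 2.72. Among repeats HERVH-int stood above the sum by 2.86, LTR7 by 2.54, HERVK-int by 1.86, LTR5_Hs by 1.68 and LTR7Y by 1.13 (adjusted p = 7.47e-05). HERV4_I-int (2.96) and L1P3b (2.24, or 1.31 without double-knockout library 2) led the 135 higher subfamilies, and both were below 0 without their top copy, at -0.45 and -0.23. UCON88 (-1.43), MER66-int (-1.39) and UCON40 (-1.28) were among the 55 lower ones. Without the top copy of each subfamily the total of 190 was 97.

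KLF5 overexpression in primed cells raised the naive list, which holds KLF5, while few genes fell far. Trophoblast and 8-cell lists also passed by camera, but not with an estimated correlation. The thyrotropin-releasing hormone gene TRH, the stress keratin KRT16, the homeobox gene MEOX1 and placental alkaline phosphatases were among the strongest rises. Of 15536 genes tested, 1570 rose and 951 fell, 672 of them at least 2-fold. KLF5 rose by 7.87±0.09, from 3.56±0.0464 to 836±41.6 CPM (adjusted p = 1.63e-20), and KLF4 by 0.74±0.15, to 6.6±1.24 CPM (adjusted p = 0.00172). NANOG rose by 0.22±0.07 (adjusted p = 0.0376), a call lost without control library 1 (0.124) or 2 (0.177) or KLF5 library 1 (0.0983) or 3 (0.165). POU5F1 (-0.14, adjusted p = 0.184) and SOX2 (-0.14, adjusted p = 0.139) did not pass, and KLF17 had too few counts to be tested. TAF11L11, a member of a tandem gene family, was at least 337-fold higher. TRH rose by 9.19±0.16 to 133±3.17 CPM, KRT16 by 8.45 (9.58 without control library 1), MEOX1 by 6.95±0.21 and S100P by 6.70±0.23. The largest falls were HMX2 (-1.32±0.14), the apelin gene APLN (-1.27±0.12), PDGFB (-1.18±0.10), SPTSSB (-0.99), ITPRID1 (-0.99) and ONECUT1 (-0.98).

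Of 22 measured naive markers, KLF5 included, 14 rose and 8 did not pass (17 rose adjusted over the list alone). The call held under both settings (adjusted p = 3.9e-12 by camera, or 0.0349 with an estimated correlation), but no test left out KLF5. ALPG rose by 5.55±0.11 (107 against 2.27 CPM) and its near-identical paralog ALPP by 5.07±0.22. Trophoblast markers rose in 10 of 20 (12 adjusted over the list alone; adjusted p = 7.79e-07, and adjusted p = 0.0928 with an estimated correlation), at low levels for TP63 (4.15±0.53; 1.12 against 0.0578 CPM) and HAND1 (3.45±0.67). The 8-cell genes rose in 5 of 7, also adjusted over the list alone (adjusted p = 0.00172, and adjusted p = 0.152 with an estimated correlation). H3Y1 was at least 21.6-fold higher, KDM4E at least 14.1-fold higher, and CCNA1 rose by 2.09±0.20. Primitive endoderm markers rose in 8 of 15 (10 rose and 1 fell adjusted over the list alone; adjusted p = 0.000266, and adjusted p = 0.098 with an estimated correlation), with APOA1 at 4.42±0.22. Interferon genes rose in 7 of 15 and fell in 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00134, and adjusted p = 0.126 with an estimated correlation), with DDX60 at 2.87±0.18 and MX1 at 2.52±0.16. WNT targets rose in 3 of 12 and fell in 1, also adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.152 with an estimated correlation), with SP5 at 3.19±0.26. Mesoderm genes rose in 5 of 10 and fell in 1 (5 and 3 adjusted over the list alone; adjusted p = 0.0246, and adjusted p = 0.176 with an estimated correlation), with TBXT at 3.65±0.36 and EOMES at 2.30. Of 15 KLF genes, KLF5 included, 5 rose (6 adjusted over the list alone), with KLF13 at 0.57±0.06. Camera adjusted p was 0.0027 (0.173 with an estimated correlation). Of 17 p53 targets 3 rose (5 adjusted over the list alone; adjusted p = 0.0399, and adjusted p = 0.236 with an estimated correlation), with GDF15 at 1.42±0.11. Primed markers fell in 11 of 24 and rose in 2 (12 and 3 adjusted over the list alone; adjusted p = 3.89e-05, and adjusted p = 0.098 with an estimated correlation), with DUSP6 at -0.81±0.07 and THY1 at -0.44±0.06.

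LTR7Y rose by 2.89±0.08 with KLF5 overexpression, from 30.9±2.37 to 228±16 CPM (adjusted p = 1.88e-13), and HERVK-int rose by 1.76±0.06 (1080 against 319 CPM; adjusted p = 1.68e-12) with LTR5_Hs at 0.87. HERVH-int (-0.04, adjusted p = 0.92) and LTR7 (-0.09, adjusted p = 0.716) did not pass, and LTR7B at 0.30 (adjusted p = 0.0444) lost its call without any one of the 6 compared libraries, at adjusted p = 0.131 to 0.281. Among 1138 subfamilies tested 19 rose and 4 fell (26 and 22 with scaling from repeats), and leaving out any one of the 6 compared libraries took this total of 23 to between 7 and 13. Of 64 LTR7Y copies 46 rose and 0 fell, and copies holding any count numbered 172 of 257 with KLF5 and 101 in the control. A copy on chromosome 19 (5552772 to 5553212), which lies 4955 bases from TINCR, was at least 188-fold higher, the chromosome X copy at 109866074 at least 175-fold higher and the chromosome 11 copy at 20572215 at least 141-fold higher. Genes known to carry LTR7 or HERVH transcripts moved apart: the calcium-binding gene CALB1 rose by 2.83±0.07 (416±10 against 58.6±5.45 CPM) and KLKB1 fell by 0.51, with 3 of 5 not passing, also adjusted over the list alone (adjusted p = 0.854).

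Primed cells with CRISPR activation aimed at LTR7Y had lower FGF and ERK response genes and higher Nodal pathway genes. None of these list calls held with an estimated correlation. DUSP6, SPRY4 and FGF19 were among the largest falls, while the BMP and Nodal antagonist CER1 and the protocadherin PCDH8 rose. Of the genes tested 4198 rose and 4231 fell (4137 and 4107 with DESeq2), 2884 of the 8429 by at least 2-fold. KLF4 rose by 2.6±0.17, from 7.37±0.539 to 44.9±5.34 CPM (adjusted p = 3.3e-10), and KLF5 by 1.83±0.16, from 2.35±0.19 to 8.34±1.41 CPM (adjusted p = 1.92e-08). NANOG fell by 0.49±0.09 (199 against 279 CPM; adjusted p = 0.00011), POU5F1 did not pass (0.05, adjusted p = 0.627), and SOX2 rose by 0.26±0.08 (adjusted p = 0.0074), a call lost without control library 2 (0.0569) or CRISPR activation library 1 (0.11). PCDH8 rose by 8.05±0.24 to 249±34.7 CPM, CER1 by 6.75±0.14 to 566±14.8 CPM, TWIST1 by 5.56 (6.18 without control library 1), the autoimmune regulator AIRE by 5.33±0.45, GARIN1A by 5.20 and TTC29 by 5.19. DUSP6 fell by 9.23±0.17, from 309±11.2 to 0.512 CPM, with values of -8.58 and -10.41 without CRISPR activation libraries 1 and 2. FGF19 fell by 6.89±0.16 (0.453 against 54.3 CPM) and SPRY4 by 6.86±0.10 (4.27±0.767 against 497±7.7 CPM). LRRC55 was 253-fold lower (95% counting interval 45.1 to 10000; -7.75, or -10.51 and -6.89 without those libraries in turn), DUSP4 fell by 6.52 (-8.00 and -5.82 in turn) and EDNRB by 6.41 (-7.21 without library 1). With 2 libraries per arm, the spread was estimated together with the KLF5 overexpression arms.

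FGF and ERK response genes fell in 17 of 17, also adjusted over the list alone (adjusted p = 2.07e-14 by camera, and adjusted p = 0.0928 with an estimated correlation), including ETV5 at -6.10±0.16. Primed markers fell in 18 of 24 and rose in 2, also adjusted over the list alone (adjusted p = 1.33e-07, and adjusted p = 0.0735 with an estimated correlation), with THY1 at -5.15±0.09 (19.7 against 696 CPM) and PTPRZ1 at -3.72±0.11. Nodal genes rose in 8 of 10 and fell in 2, also adjusted over the list alone (adjusted p = 3.89e-05, and adjusted p = 0.126 with an estimated correlation), with LEFTY2 at 4.16±0.10 (781 against 43.7 CPM) and LEFTY1 at 2.61±0.11. Naive markers rose in 12 of 22 and fell in 5, also adjusted over the list alone (adjusted p = 0.0188, and adjusted p = 0.157 with an estimated correlation), with ALPP at 3.10±0.35. KLF family genes rose in 9 of 15 and fell in 4, also adjusted over the list alone (adjusted p = 0.0478, and adjusted p = 0.326 with an estimated correlation), with KLF2 at 3.01±0.31 and KLF15 at -2.25±0.15. DNA methylation genes fell in 8 of 12 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0149, and adjusted p = 0.158 with an estimated correlation), with UHRF1 at -1.59±0.10 and TET1 at -1.41±0.11. Shared pluripotency genes fell in 8 of 13 and rose in 3, also adjusted over the list alone (adjusted p = 0.0394, and adjusted p = 0.505 with an estimated correlation), with JARID2 at -1.82±0.09. Mitochondrially encoded genes rose in 11 of 13, also adjusted over the list alone (adjusted p = 3.71e-05, and adjusted p = 0.236 with an estimated correlation), with MT-ND1 at 0.58±0.07. Library composition moved as well: these genes held 9.61% of the counts with activation and 7.6% in the control, and the 10 most counted genes held 11.6% and 9.42%. Among genes known to carry LTR7 or HERVH transcripts, CALB1 rose by 3.08±0.09 (452±34 against 53.6±3.49 CPM), and as a list 2 of 5 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.138).

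LTR7Y rose by 2.75±0.11, from 15.6±0.0513 to 105±2.01 CPM (adjusted p = 9.02e-12). HERVK-int rose further, by 3.55±0.08 (3540±181 against 303±13.9; adjusted p = 4.08e-15), and LTR5_Hs rose by 2.07±0.08 (603±50.2 against 144±8.9; adjusted p = 1.07e-11). HERVH-int fell by 0.29 (adjusted p = 0.00187), and LTR7 fell by 0.30 (adjusted p = 0.004), a call lost without control library 2 (0.0686). In all, 296 subfamilies rose and 49 fell (166 and 155 with scaling from repeats), with HERV4_I-int at -3.05, MER34-int at -2.20, LTR1F at -1.13 and HAL1ME at -0.83. This total of 345 was 130 and 158 without control libraries 1 and 2, and 647 and 209 without CRISPR activation libraries 1 and 2. Without the top copy, HERV4_I-int read 0.5, LTR1F 0.77 and HAL1ME 0.38, and outside gene bodies MER34-int read 0.52 and HAL1ME 0.69. The satellite ALR/Alpha rose by 1.85 (155±159 CPM), a value that was -0.02 without CRISPR activation library 2 and 2.64 without library 1, and its call was lost without control library 1 (0.0768) or 2 (0.0611). Of 64 LTR7Y copies 26 rose and 5 fell. The chromosome 9 copy at 82701562 was at least 97.5-fold higher, the CALB1 copy at 90090224 at least 54.9-fold higher and a copy on chromosome X (4540474 to 4540914) at least 46.9-fold higher, while the NTN4 copies fell by 2.26 and 1.69.

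The changes with KLF5 overexpression and with LTR7Y activation were set against those between naive and primed cells, gene by gene. Of 2059 genes called with KLF5 overexpression and in the naive-primed comparison, 72.2% moved in the same direction (odds ratio 8.46, Fisher exact p = 3.12e-104, adjusted p = 4.45e-104 over 10 pairs; Pearson 0.304 and Spearman 0.29 across genes). For LTR7Y activation it was 56.9% of 6792 genes (odds ratio 1.73, Fisher exact p = 4.31e-29, adjusted p = 4.78e-29; Pearson 0.22, Spearman 0.157). Both treatments moved 68.6% of 1587 jointly called genes in the same direction (odds ratio 5, Fisher exact p = 3.43e-52, adjusted p = 4.29e-52). KLF5 overexpression in primed cells and KLF5 knockout in naive cells moved 61.1% of 1559 genes in opposite directions (odds ratio 0.295, Fisher exact p = 5.85e-28, the same when adjusted), although across genes Pearson was -0.0388 and Spearman -0.156. CALB1 rose with both treatments and fell with knockout of KLF4 (-2.36±0.13), of KLF5 (-2.02±0.12) and of both (-2.23±0.12). These p-values treat genes as independent, which they are not.

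**Figure D4:**
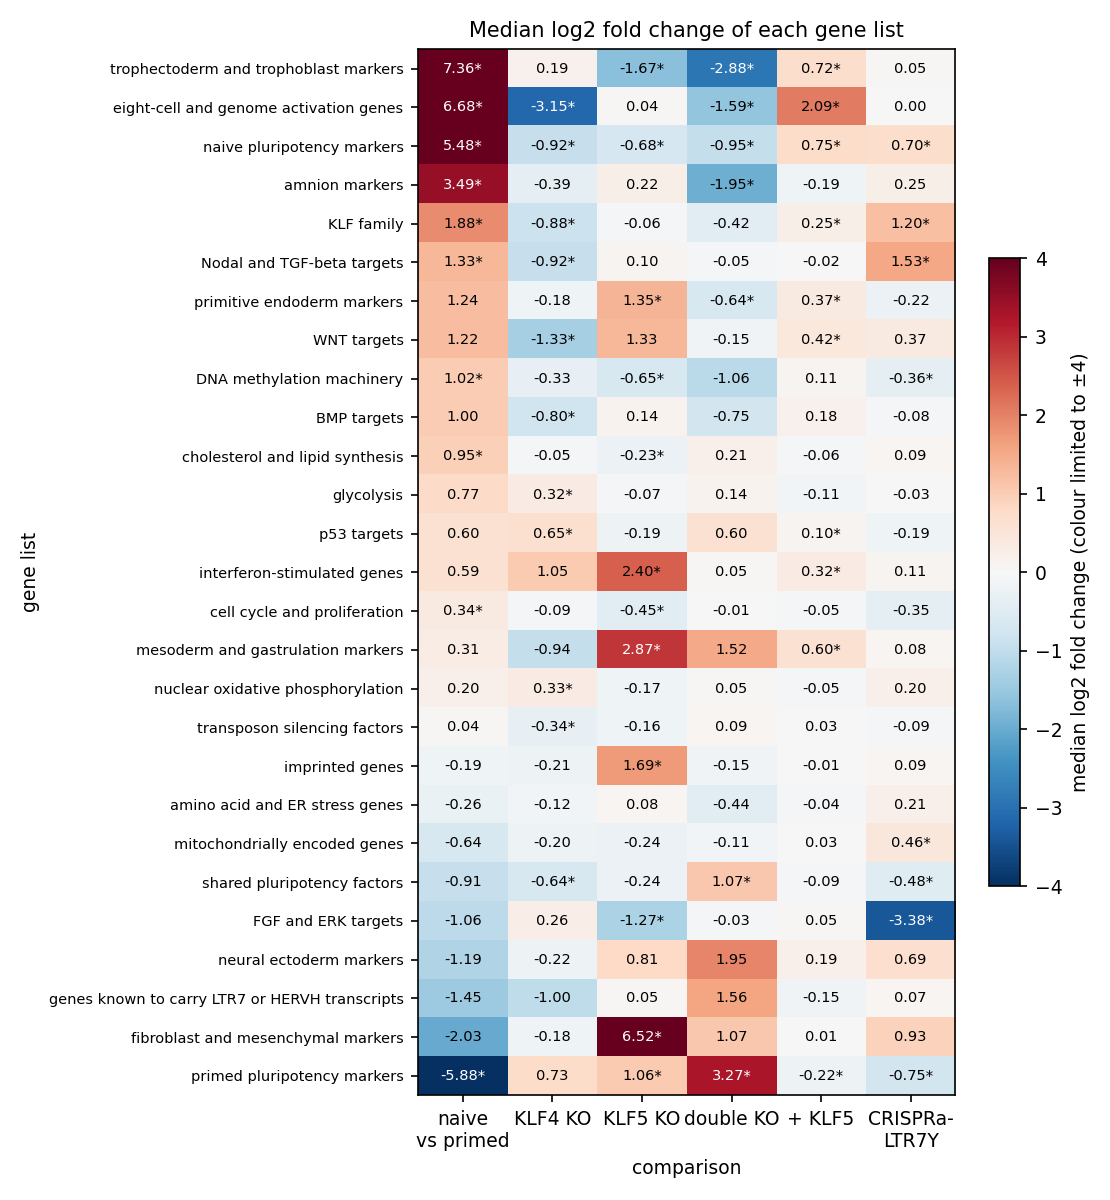
Median log2 fold change of each of the 27 gene lists (vertical axis) in 6 comparisons (horizontal axis), with colour limited to ±4. An asterisk marks a camera adjusted p under 0.05. Over all 8 comparisons 3 of 88 such calls held with an estimated correlation.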

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

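The tests of fibroblast and mesodermal genes below were chosen after the KLF5-knockout result was seen, as was the count over copies outside gene bodies; the other tests were set beforehand.

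A difference between groups stood out in the interaction test, which set the double knockout against the sum of the single ones. It called 6586 genes and 190 repeat subfamilies (97 without the top copy of each, where no groupings were drawn). Of 100 drawn groupings, the real one included, 1 gave as many (highest other 2972 genes and 78 subfamilies). Groupings also mix single-knockout effects, so chance in the interaction stays open. NANOG departed from the sum of the single knockouts by 2.02, POU5F1 by 1.75, SOX2 by 2.31 and KLF5 by -0.96. Departures far above the sum were GAL3ST3 at 7.8 (8.47 without KLF5-knockout library 1) and the chemokine gene CXCL5 at a fitted 7.73 (0 CPM in KLF4-knockout cells). Those far below were SAMD9L at a fitted -12.86 (0 CPM in naive wild-type cells), the proteoglycan gene FMOD at -10.97 and DCN at -10.64 (-11.75 without naive library 1). Repeats departed by 2.86 for HERVH-int, 2.54 for LTR7, 1.86 for HERVK-int, 1.68 for LTR5_Hs and 1.13 for LTR7Y.

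Comparisons of 3 libraries against 3 have 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave the value. Real gene counts were 12319, 7578, 8263, 10254, 8798 and 2521 for the naive-primed, KLF4-knockout, KLF5-knockout, double-knockout, KLF5 against KLF4 knockout and KLF5 overexpression comparisons, and the highest other was 0 in each. For subfamilies they were 711, 286, 249, 471, 342 and 23, with 0 as the highest other except 1 for the double knockout. For LTR7Y copies they were 34, 28, 18, 26 and 46, with 0 as the highest other; the KLF5 against KLF4 comparison was not counted by copy.

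Mesenchymal genes rose in KLF5-knockout cells, with COL3A1 at 9050±2900 CPM. Fibroblasts from outside the line would bring identity genes of adult fibroblasts. Of 12 such genes 9 were measured and 6 rose, with a median of 1.62. PRRX1 went from 0 to 0.892 CPM (0.861 in primed wild-type cells), and TWIST2 fell by 0.55 from 18.6 CPM. This source stays open, as do reads of another species, which were not tested. Mesodermal genes of extraembryonic type, tested for a change in cell state inside the line, had a median of 3.21 with 9 of 14 risen, among them HAND2 (7.87), FOXF1 (7.42) and TCF21 (0.0186 to 13.1 CPM). That list was chosen after the values were seen, so its rise is no independent check. Naive wild-type cells already expressed part of that list, with HAND1 at 377 CPM, PITX1 at 235 CPM and TBX3 at 557 CPM, and TBX3 fell by 1.62 in the knockout. A change of state within the line cannot be told apart from outside fibroblasts.

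Double-knockout cells lay between the naive and primed states. A share of primed cells in the culture would place genes at 1 common position between the states, but genes at least 16-fold higher in primed cells lay at a median of 0.172 of the way and those at least 16-fold higher in naive cells at 0.833, a difference of 0.661 that argues against a mixture as the whole cause. The position did not rest on 1 library, since the share of primed-high genes that rose kept at least 0.953 of its value (69% in full, 65.8% without double-knockout library 3). That line was also 1 passage later than the others, which was not tested.

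HERVK-int and LTR5_Hs rose with CRISPR activation aimed at LTR7Y. Scaling from repeats did not remove it (HERVK-int 3.37, LTR5_Hs 1.9). Without the top copy HERVK-int read 3.44 and LTR5_Hs 1.55, and outside gene bodies 3.01 and 1.58. Reads counted at several copies leave a single-copy or genic source open. With 2 libraries per arm, no test by splits was made. With KLF5 overexpressed (836 CPM, here 8.34) HERVK-int rose less, by 1.76. A downstream response and guide binding at LTR5_Hs were not tested.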

How the results depend on the processing

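Copies outside gene bodies, and leave-outs for the overlaps, were chosen after seeing the data; the other alternatives were planned. Gene results were stable to the method: 883 of the named gene values kept direction and call with DESeq2 and 7 lost the call, 887 and 4 did so with RLE size factors, 889 and 2 without a count filter, and 845 and 8 with only the groups compared. No named gene and no overlap reversed under the alternatives run. Leaving out 1 library at a time kept 5562 gene values, while 244 lost the call. Gene counts ranged from 6344 to 6857 for the KLF4 knockout, from 7169 to 7950 for the KLF5 knockout, from 1714 to 2256 for KLF5 overexpression and from 6945 to 8339 for CRISPR activation. The balance of rises and falls for the KLF4 knockout turned from 3906 and 3672 to 3843 and 3978 with DESeq2, and to 3679 and 3867 with RLE size factors. For CRISPR activation 4198 and 4231 turned to 4137 and 4107, and to 4250 and 4173. RLE scaling moved the median gene by at most 0.03. Of 88 list calls, 3 held with the estimated correlation. On simulated data for the KLF5 knockout, 34% of copies and 94% of subfamilies changed 2-fold were recovered.

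Over 20 pairs of groups the correlations between same-numbered libraries lay between -0.127 and 0.237, with 4 over 0.1, and in 9 of 20 the best partner had the same number. With the replicate block the gene counts were 12299, 7459, 8188, 10178, 8757 and 6523 for the naive-primed, KLF4-knockout, KLF5-knockout, double-knockout, KLF5 against KLF4 and interaction comparisons, 3128 with KLF5 overexpression and 8804 with CRISPR activation. The KLF family list with CRISPR activation lost its call in that fit (adjusted p = 0.0794, against 0.0478 without the block and adjusted p = 0.326 with an estimated correlation).

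Subfamily counts moved more, and the cause was not tested. The KLF4-knockout count of 286 ranged from 174 (without naive library 2) to 267 over leave-outs. The KLF5-knockout count of 249 ranged from 164 (without KLF5-knockout library 1) to 230 and was 153 without the top copy, where the interaction count of 190 was 97. With KLF5 overexpression the count of 23 was 48 with scaling from repeats, 12 without the top copy, 49 outside gene bodies, 70 with only the groups compared, and 7 to 13 over the 6 leave-outs. With CRISPR activation the count of 345 was 91 with only the groups compared and 130 to 647 over the leave-outs. Such a leave-out leaves 1 library in an arm, which is assumed to vary like the other groups. ALR/Alpha with CRISPR activation lay between -0.02 (without activation library 2) and 2.64 (without library 1). LTR7Y copies called numbered 64 at a minimum of 10 counts in the naive-primed comparison, where more copies were tested, and 11 (without KLF5-knockout library 1) to 19 for the KLF5 knockout.

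Scaling from repeats shifted subfamilies by -0.186 with CRISPR activation and turned 296 rises and 49 falls into 166 and 155.

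Reversals were found in repeats that rest on genic or single copies. Outside gene bodies, LTR10B2 read -0.19, 0.08 and 0.52 in the naive-primed, KLF5-knockout and double-knockout comparisons, and LTR5 read 0.69, 0.53 and 1.28 in the KLF5-knockout, double-knockout and KLF5 against KLF4 comparisons. MER66-int read -0.98 (naive-primed), 0.15 (KLF5 knockout) and 0.25 (KLF5 against KLF4). HERV17-int read 1.67 in the double knockout and 0.66 for KLF5 against KLF4, HERVK-int -0.05 in the double knockout, MLT1G-int -0.02 in the KLF4 knockout, UCON34 0.82 in the interaction, and MER34-int 0.52 and HAL1ME 0.69 with CRISPR activation. Without the top copy, HERV17-int read 0.23 and 0.52 in those 2 comparisons, L1P3b 0.45 in the KLF4 knockout and -0.23 in the interaction, and LTR5A -0.13 in the double knockout and -0.26 in the interaction. HERV4_I-int read -0.45 in the interaction, 0.18 with KLF5 overexpression and 0.5 with CRISPR activation, UCON34 0.2 in the interaction, and LTR1F 0.77 and HAL1ME 0.38 with CRISPR activation.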

Other observations

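Lineage and metabolic lists outside the main text moved without a common direction. Neural ectoderm markers passed in no comparison as a list: in naive cells 4 rose and 6 fell of 12, also adjusted over the list alone (adjusted p = 0.511 by camera), with the homeobox gene DLX5 at 9.01±0.55 against the microtubule gene MAP2 at -6.22±0.58. In the double knockout 7 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.672), with FABP7 at -3.54±0.30. With CRISPR activation 5 of 13 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.3), and the list had a median of 0.69 and a mean of -0.07; MAP2 rose by 2.52±0.14. Amino acid and ER stress genes rose in 7 of 16 and fell in 7 in naive cells, also adjusted over the list alone (adjusted p = 0.84), with the chaperone gene DNAJB9 at 2.98±0.19 and the serine synthesis gene PHGDH at -2.49±0.10. In the double knockout they fell in 9 and rose in 4, also adjusted over the list alone (adjusted p = 0.157), with TRIB3 at -1.76±0.15, and with CRISPR activation they rose in 8 of 15 and fell in 4, also adjusted over the list alone (adjusted p = 0.0989), with the stress gene DDIT4 at 2.28±0.11 and ATF3 at 1.69±0.12.

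Glycolysis genes moved both ways in naive cells. ENO2 fell by 2.86 and PFKM by 2.71, while PGAM1 rose by 2.49±0.10, and as a list 12 of 18 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.0546). ENO2 and PFKM rose again in the double knockout, by 2.93±0.18 and 2.23±0.13. Mitochondrially encoded genes fell in 8 of 13 in naive cells, also adjusted over the list alone (adjusted p = 0.0844), and their share of gene counts in the double-knockout libraries ran from 5.76% to 9.9%, the latter in library 2. Imprinted genes moved both ways in naive cells, with 5 risen and 5 fallen of 14, also adjusted over the list alone, a median of -0.19, a mean of 0.45 and adjusted p = 0.938; the growth inhibitor gene CDKN1C rose by 4.74±0.16 and the transporter gene SLC38A4 fell by 6.47. CDKN1C also rose by 4.54±0.13 with CRISPR activation and fell by 2.5 in the double knockout. The imprinted gene DLK1 rose by 4.06±0.17 with KLF5 overexpression and by 8.96±0.39 with KLF5 knockout. Genes known to carry LTR7 or HERVH transcripts rose in 4 of 5 in the double knockout and fell in 1, also adjusted over the list alone (adjusted p = 0.414).

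Older and other young repeat families followed the states unevenly. In naive cells, SVA subfamilies rose in 4 of 6 and fell in 1, AluY in 8 of 14 with 2 fallen, young L1 in 3 of 8 with 3 fallen, HERVW and HERV-FRD LTRs in 5 of 8 with 2 fallen, MLT2 and HERVL in 1 of 9 with 6 fallen, LTR12 and HERV9 in 2 of 10 with 7 fallen, and trophoblast LTRs in 2 of 19 with 10 fallen. SVA fell in 5 of 6 with KLF4 knockout and again in the double knockout, and rose in 3 of 6 with KLF5 knockout. HERVW and HERV-FRD LTRs fell in 6 of 8 in the double knockout. Young L1 rose in 7 of 8 with CRISPR activation and in 0 of 8 with KLF5 overexpression. The LTR7 and HERVH list gave 2 rises and 4 falls of 6 in naive cells and 3 rises and 2 falls in the double knockout, and the LTR5 and HERVK list gave 3 rises and 1 fall of 5 in naive cells and 5 falls with KLF4 knockout.

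Levels in primed wild-type cells and the transfected controls differed, also between the controls of the second experiment. HERVH-int stood at 28700±969 CPM in primed wild-type cells, at 53700 CPM in the KLF5 overexpression controls and at 40900 CPM in the CRISPR activation controls, and LTR7Y at 32.2±2.3, 30.9±2.37 and 15.6±0.0513 CPM. NANOG stood at 56.1±5.27 CPM in primed wild-type cells and at 255 and 279 CPM in the transfected controls. The experiments were fitted apart, and these levels were not compared by a test. LTR7Y counts came from few copies, since the top copy held 8.7% to 23.4% of them and the top 5 held 39.2% to 61% across groups.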
